A study of Mus musculus with 18 samples.

How the data were processed

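Total RNA and polysome-bound RNA were sequenced from 2 sorted populations of mouse MDSC and from bone marrow, in 18 libraries of 6 groups with 3 biological replicates each. Sorted cells came from bone marrow cultured for 5 days, and were collected the day after sorting in the presence of cycloheximide, which holds ribosomes on their mRNA. Marrow was flushed from femurs and freed of red cells by lysis. Polysomes were separated on a sucrose gradient, and stranded libraries were made after depletion of ribosomal RNA.

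The deposited file holds raw counts, as the authors' table of 54838 genes by 18 libraries. The authors list FastQC, STAR, DESeq and DESeq2 with the GRCm38 genome. Which program counted the reads, with which annotation and strand setting, is not given in the sources used here. Gene names, classes and coordinates came from GENCODE M21, which matched 54809 identifiers and left 29 without a name. No reads were mapped again.

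Counts were fitted in R 4.3.3 with edgeR 4.0.16, and figures were drawn with matplotlib 3.10.9. All 18 libraries entered 1 model with a mean for each of the 6 groups and no block. Genes passed the filter of filterByExpr with a minimum count of 10, which kept 14181. TMM factors scaled the libraries, and a prior count of 2 was used for log2 CPM. The common dispersion was 0.163. Robust quasi-likelihood F tests gave p values, adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The 12 comparisons were LY6G with LY6C, LY6C with BM and LY6G with BM in each fraction, polysomal with total RNA in each kind of cell, and the 3 differences of those polysomal minus total contrasts, here called translational efficiency. Log2 differences are given with their standard error, and group levels as mean ± SD of CPM. For a gene with 0 counts in a group, the floor of a fold took 3 counts over that group, the upper limit at 95% confidence, against the lower of the other group's mean CPM and its pooled counts per library size. With 1 to 3 counts the ratio of pooled counts is given with its exact counting interval.

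The 29 gene lists, written before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with a correlation estimated for each list, and with fry, which tests whether the genes of a list move one way and does not compare them with other genes. Lists needed 3 tested members, and p values were adjusted over the lists of a comparison. Named genes followed a rule written before the data were examined. They had an adjusted p under 0.05, a mean of at least 10 CPM in the highest group and no overlap between groups, and gene models without a name were skipped. The largest rises and falls were taken, up to 12 each for total RNA, 8 each for polysomal minus total and for efficiency and 5 each for polysomal RNA, with up to 4 members of each list. Itgam, Ly6g, Ly6c1, Ly6c2, Arg1 and Nos2 were followed whatever their values. The text gives a part of these genes, and some items are not reported here.

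Alternatives written before the data were examined were DESeq2 1.42.0, limma voom with quality weights, median-ratio factors, no filter, a filter of 50 counts in 3 libraries, a fit of the compared libraries alone, leaving out 85 genes (37 mitochondrial and the 50 most abundant, some counted in both), a replicate block, and leaving out each library in turn. Chosen after seeing the data were the block in the compared libraries alone, thinning to 128251 counts a library, leaving out replicate 6 and lists of annotated noncoding RNA classes. A library left alone beside 1 other is assumed to vary like the rest, since the fit pools the spread over groups.

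Pairing came from the replicate numbers in the sample names. It was checked as the correlation of each library's deviations from its group mean between libraries that share a number, against a threshold of 0.1. Within LY6C the correlations of polysomal with total RNA were 0.70, 0.68 and 0.60, and within LY6G 0.56, 0.73 and 0.74. LY6G with LY6C gave 0.42, 0.45 and 0.59 in total RNA and 0.27, 0.38 and 0.47 in polysomal RNA. The numbers thus pair the sorted-cell libraries. Bone marrow fractions gave 0.03, 0.01 and 0. In BM total RNA only 1710 ± 280 genes reached 10 counts, so few genes could carry a correlation. The check cannot decide whether the numbers pair there. The planned fit without a block was kept for all comparisons, so in sorted cells it leaves this pairing out. The lack of a called gene there does not show that the groups are alike. Results with the replicate number as a block are given beside it.

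Depth sets the precision. One CPM was 0.472 to 0.611 counts in BM total RNA, 1.73 to 3.51 in BM polysomal RNA and 18 to 110 in sorted cells. The edgeR fits with and without the block were tested on simulated data in which 200 genes changed, in 8 of the 12 comparisons. LY6G minus BM in total RNA, polysomal RNA and efficiency, LY6C minus BM in polysomal RNA, DESeq2 and limma were not simulated. Changed genes were drawn from those with a mean of at least 1 CPM. Simulated BM total libraries took the mean rates of LY6C total or BM polysomal RNA at their own size. The real difference in composition between BM total RNA and these groups was therefore absent from the simulation. Without the block edgeR recovered 88% of 8-fold and 1% of 2-fold changes in LY6G minus LY6C total RNA, 70% and 0% in LY6C minus BM total RNA, 93% and 1% in polysomal minus total RNA of LY6C, 55% and 2% in that of BM, 58% and 0% in efficiency between LY6G and LY6C and 38% and 1% in efficiency between LY6C and BM. Unchanged genes made up 7.89% of the simulated calls in LY6C minus BM total RNA (6 of 76) and 9.52% in polysomal minus total RNA of BM (6 of 63). With the replicate block they were 8.76% (12 of 137), 6.67% (9 of 135) and 5.36% (3 of 56) in polysomal minus total RNA of LY6C, LY6G and BM. In LY6G minus LY6C the block gave 7.04% (10 of 142) in total RNA, 9.42% (13 of 138) in polysomal RNA and 11.1% (12 of 108) in efficiency. Each lies above the 5% set, but each comparison was simulated once and few genes stand behind each share. At 2-fold the block recovered 34% and 29% of changes in LY6G minus LY6C total and polysomal RNA. In polysomal minus total RNA of LY6C and LY6G it recovered 25% and 29%. Libraries were checked for duplicates, and none were found (lowest chi-squared per degree of freedom 36.3). Mapping, read quality, isoforms and the protein level were not analysed here.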

Results

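RNA sequencing measured total RNA and polysome-bound RNA, the RNA carried by several ribosomes at once, in 3 kinds of mouse cells. Myeloid-derived suppressor cells (MDSC), immature myeloid cells that hold back T cell responses, were grown from bone marrow for 5 days and sorted. The population named LY6G was high in Ly6G and intermediate in Ly6C, and the population named LY6C lacked Ly6G and was high in Ly6C. Unsorted bone marrow (BM) was the third kind of sample. Each kind gave 3 total and 3 polysomal libraries, so 18 libraries fell into 6 groups of 3. Replicates of the sorted cells carried the numbers 2, 3 and 6, and those of bone marrow the numbers 1, 2 and 3.

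Total counts, in the order of these numbers, were 21138649, 8684335 and 8559897 for LY6C total RNA and 20313012, 11677465 and 8857832 for LY6C polysomal RNA. LY6G total RNA had 17038444, 15148630 and 16247718 counts, and LY6G polysomal RNA 18268197, 20552964 and 19085627. Bone marrow total RNA had 19776431, 26225431 and 25058990 counts, and bone marrow polysomal RNA 17846803, 15125180 and 12107504.

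Ribosomal RNA took up most of the bone marrow libraries. Mitochondrial ribosomal RNA held 61.3% ± 4.35 of the counts in BM total RNA (mean ± SD, n = 3) and 35.4% ± 7.17 in BM polysomal RNA, and nuclear loci that resemble ribosomal RNA held 38.2% ± 4.31 and 61.2% ± 7.48. Protein-coding genes were left with 0.267% ± 0.031 of BM total and 2.96% ± 1 of BM polysomal counts, or 63200 ± 11500 and 441000 ± 162000 counts a library. These values leave out Lars2, which is annotated as protein coding but was placed among the nuclear loci that resemble ribosomal RNA. Lars2 had 751640, 652990 and 579289 counts in BM total and 767792, 715812 and 452656 in BM polysomal libraries. In sorted cells the protein-coding share was 61.7% ± 28.7 in LY6C total, 77.6% ± 14.2 in LY6C polysomal, 79.8% ± 8.93 in LY6G total and 92.8% ± 1.66 in LY6G polysomal RNA. At least 10 counts were reached by 1710 ± 280 genes in BM total RNA, 6440 ± 1100 in BM polysomal RNA and 11900 to 13500 genes, as group means, in sorted cells.

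**Figure D1:**
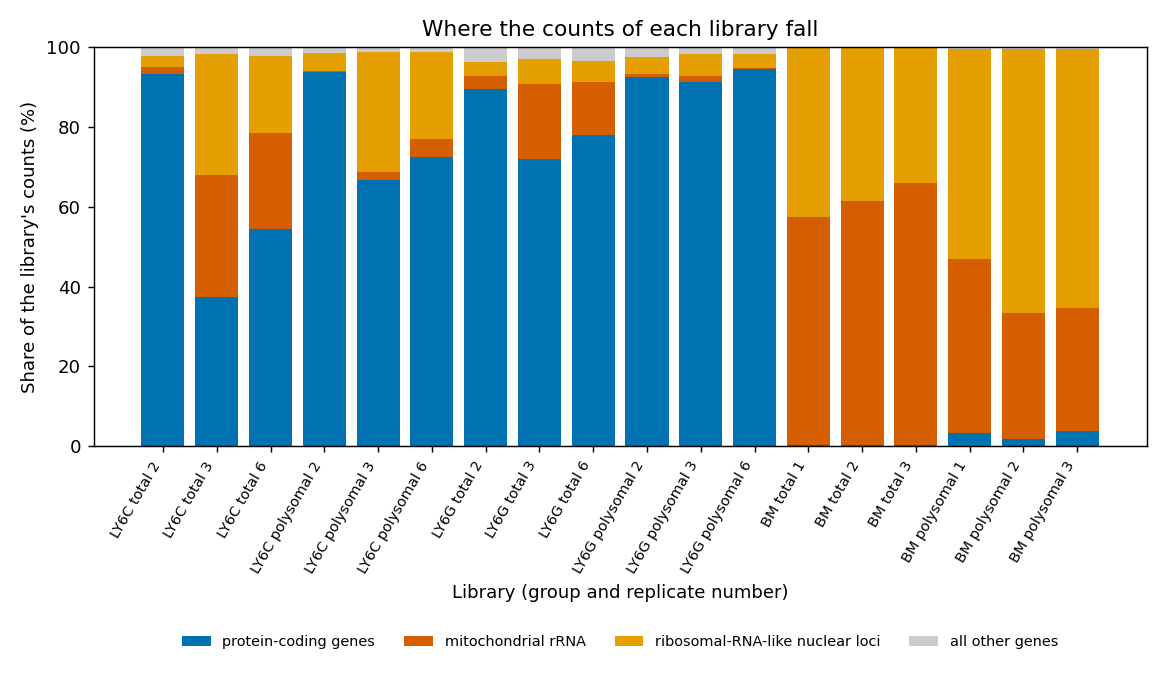
Share of each library's counts (vertical axis, percent, from 0 to 100) in protein-coding genes, mitochondrial ribosomal RNA, nuclear loci that resemble ribosomal RNA and all other genes, with 1 bar per library. Protein-coding genes, without Lars2, which is placed among the nuclear loci, hold a mean of 0.267% in bone marrow total RNA and 92.8% in LY6G polysomal RNA.

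Levels are CPM, counts scaled to a common library size by TMM factors, and all intervals and floors cover counting error only. One CPM corresponded to 0.472 to 0.611 counts in a BM total library, so a gene with 0 counts there was not detectable at this depth rather than absent. Genes followed in every comparison were Itgam (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491, build GRCm38), Ly6g (ENSMUSG00000022582, chromosome 15, 75155240 to 75159126), Ly6c1 (ENSMUSG00000079018, chromosome 15, 75044018 to 75048830) and Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) and Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254) were followed too. Other genes that the text returns to are Csf1r (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149), Slc4a1 (ENSMUSG00000006574, chromosome 11, 102348824 to 102366203), Ddhd1 (ENSMUSG00000037697, chromosome 14, 45588467 to 45658143) and mt-Nd5 (ENSMUSG00000064367, chromosome M, 11742 to 13565).

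The comparison of LY6G with LY6C total RNA asks which transcripts separate the 2 MDSC populations. Ly6g, the antigen of the LY6G gate, stood at 4.03 ± 4.07 CPM in LY6G and 3.38 ± 1.34 in LY6C (mean ± SD, n = 3 each). Only number 6 put LY6G above LY6C (8.73 against 4.16 CPM), while numbers 2 and 3 had 1.62 and 1.73 CPM in LY6G against 1.84 and 4.16 in LY6C. Itgam, which encodes CD11b, was at 52.4 ± 8.32 and 42.7 ± 10.3. Ly6c2, a gene of the Ly6C antigen, was at 58.3 ± 10.8 CPM in LY6G and 84.2 ± 9.2 in LY6C, a log2 difference of −0.53 ± 0.48 (SE), with LY6C higher in every replicate number of both fractions. Arg1 and Nos2, enzymes that use up arginine and serve T cell suppression, varied more within than between populations, with Arg1 at 77.3 ± 112 against 98.6 ± 163 CPM and Nos2 at 9.62 ± 14.5 against 42.5 ± 72.1 (adjusted p = 1 for all 5 genes).

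**Figure D2:**
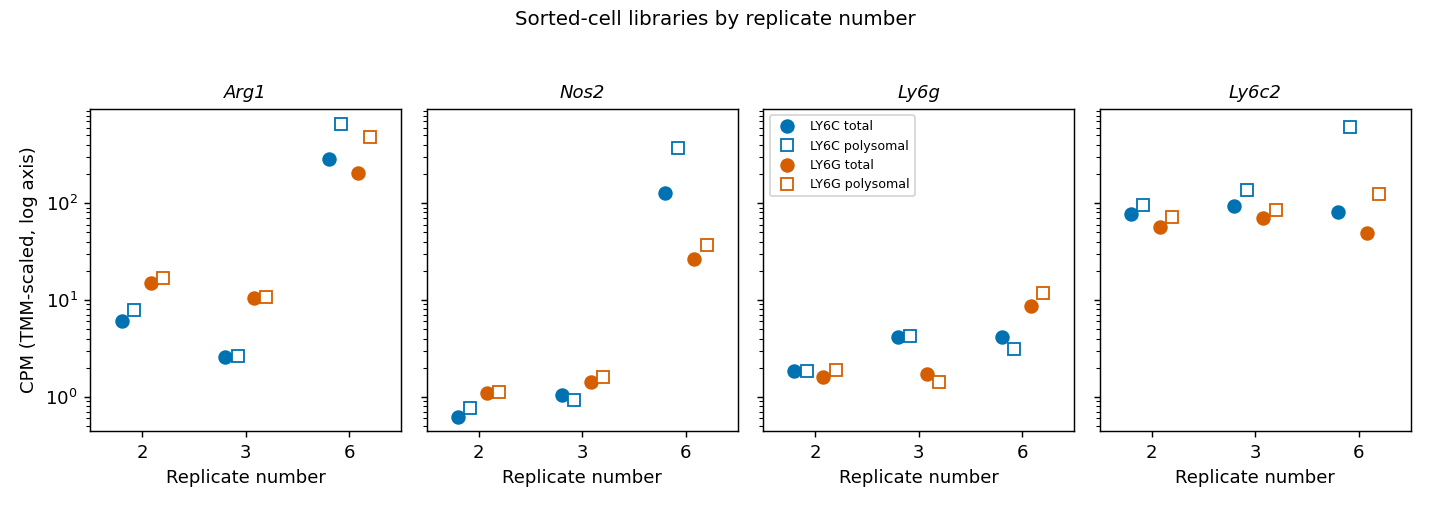
CPM on a log axis of Arg1, Nos2, Ly6g and Ly6c2 in the 12 sorted-cell libraries, by replicate number (2, 3 or 6), with populations and fractions marked apart. Arg1 lies between 206 and 661 CPM in the 4 libraries numbered 6 and at 16.9 CPM or below in the others.

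Several gene lists leaned to LY6C without a called member, and the LY6C libraries numbered 3 were high in most of them, with medians against the other LY6C libraries of 3.57 for primary granule, 1.63 for cell cycle, 1.8 for histone, 1.16 for cholesterol synthesis and 1.09 for neutrophil maturation genes. All 31 cell cycle genes had negative log2 differences, with a median of −0.72 (camera adjusted p = 7.44e-07, adjusted p = 0.586 with an estimated correlation). Neutrophil primary granule genes, which encode the enzymes of early granules, had a median of −2.59 over 8 members (adjusted p = 0.000996, and 0.586 with an estimated correlation), and 26 neutrophil maturation genes −0.48 (adjusted p = 0.000208, and 0.534 with an estimated correlation). Replication-dependent histone genes gave −0.68 (adjusted p = 0.000208, and 0.866 with an estimated correlation) and cholesterol synthesis genes −0.45 (adjusted p = 0.00121, and 0.684 with an estimated correlation). Inflammatory cytokine and chemokine genes leaned to LY6G, with 24 of 29 members positive and a median of 0.40 (adjusted p = 0.00121, and 0.586 with an estimated correlation). Against the other LY6C libraries, those numbered 3 had a median of −1.52 in this list and those numbered 6 of 1.24. Genes of MDSC suppressive function had a median of 0 over 24 members (adjusted p = 0.657). With the replicate number as a block, ribosomal protein genes also leaned to LY6G, at a median of 0.19 (adjusted p = 0.0243 against 0.0646 without the block, and 0.822 with an estimated correlation). One erythroid gene was lower adjusted over the list alone, and no other list had a member that passed in this way.

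Of 14181 genes tested, edgeR's quasi-likelihood test called 0 after Benjamini-Hochberg adjustment, with 565 at an unadjusted p under 0.05. DESeq2 called 0, limma called 1, and the fit without a filter on low counts called 76. Median-ratio factors moved the median log2 difference of all genes to 0.146 here and 0.132 in polysomal RNA.

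In polysomal RNA, the same contrast asks which transcripts under translation separate the populations. Ly6c2 was at 92.8 ± 26.7 CPM in LY6G and 283 ± 290 in LY6C (log2 difference −1.61 ± 0.49, adjusted p = 0.841), where the LY6C mean rested on the library numbered 6 at 617 CPM, without which the difference was −0.33. Ly6g stood at 5.01 ± 5.8 against 3.08 ± 1.21 CPM and Itgam at 40.3 ± 1.88 against 27.3 ± 13.3. Arg1 was at 168 ± 267 against 224 ± 379 CPM, and Nos2 at 13.3 ± 20.6 against 124 ± 214. Lists that leaned to LY6C included cell cycle, with a median of −0.85 (adjusted p = 4.11e-07), replication-dependent histones, −1.03 (adjusted p = 4.23e-08), nuclear genes of oxidative phosphorylation, −0.42 (adjusted p = 4.06e-06), and glycolysis and hypoxia, −0.51 (adjusted p = 0.00381). Each of these 4 had an adjusted p = 0.582 with an estimated correlation, and 1 B cell gene was lower adjusted over the list alone. Single LY6C numbers stood above the other LY6C libraries, over both fractions. Number 3 did so in cell cycle (median 1.63), histone (1.8) and oxidative phosphorylation genes (0.38), and number 6 in glycolysis and hypoxia genes (1.04). When the replicate number was a block, inflammatory genes leaned to LY6G (median 0.26, adjusted p = 0.0195 against 0.106 without the block, and 0.592 with an estimated correlation). Immediate early and stress genes then leaned to LY6C (median −0.24, adjusted p = 0.0475 against 0.0608, and 0.518 with an estimated correlation).

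The quasi-likelihood test of edgeR called 0 genes in polysomal RNA, with 833 at an unadjusted p under 0.05 and a lowest adjusted p of 0.432. DESeq2 and limma called 0, and the fit without a filter called 88. Across the 14181 genes, which are not independent replicates, the LY6G minus LY6C log2 differences of total and polysomal RNA had Pearson's r = 0.75 and Spearman's rho = 0.77.

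**Figure D3:**
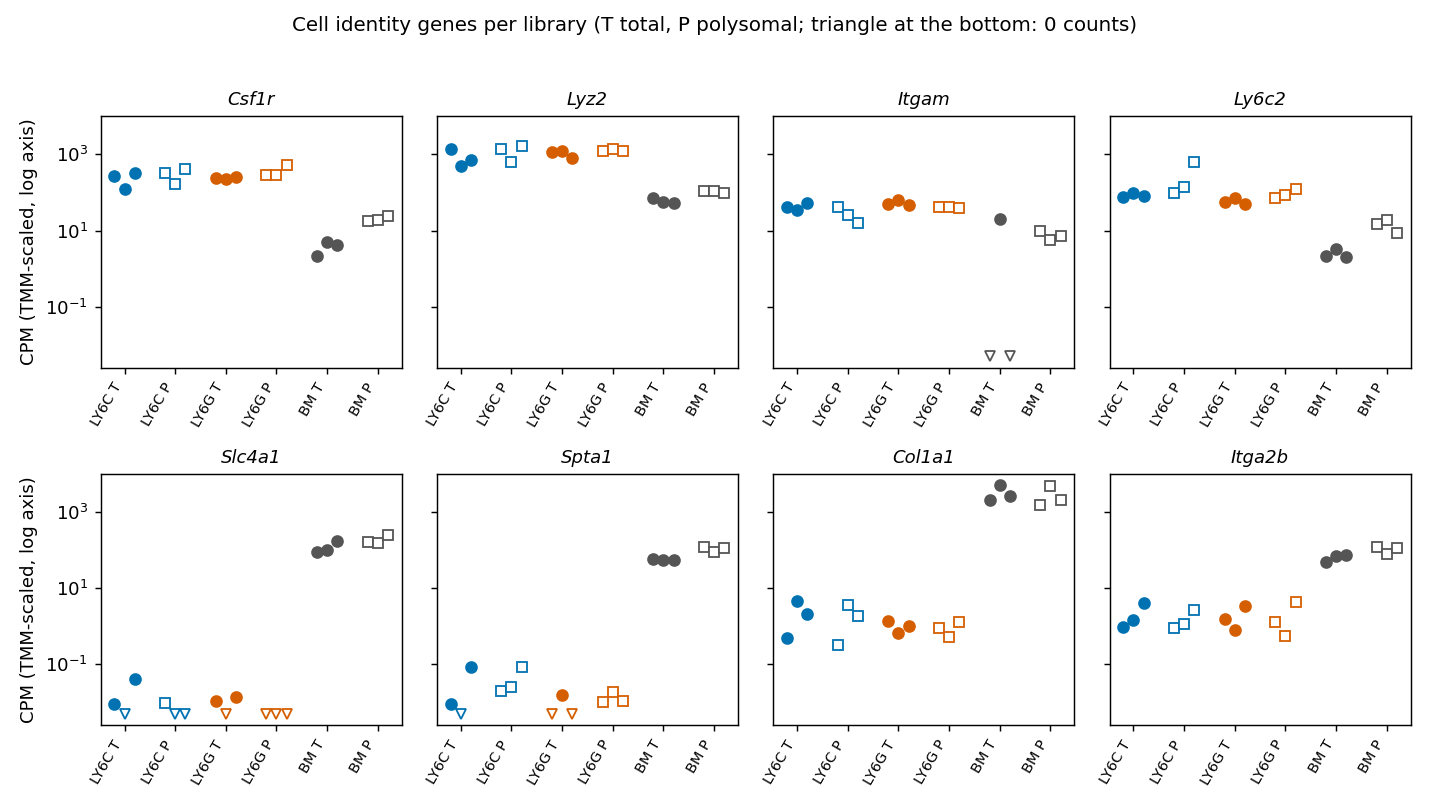
CPM on a log axis of 8 genes of cell identity in each of the 18 libraries, by group (T total RNA, filled circles; P polysomal RNA, open squares; triangles, 0 counts). Csf1r and Lyz2 are higher in all 12 sorted libraries than in any bone marrow library, while Slc4a1 and Col1a1 are higher in all bone marrow libraries.

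Comparing LY6C with bone marrow in total RNA asks what distinguishes the LY6C population from bone marrow. Csf1r, the receptor of the macrophage growth factor, was at 242 ± 107 CPM against 3.72 ± 1.44 in BM (63.6-fold, adjusted p = 2.59e-07, n = 3 each, edgeR). Lyz2, lysozyme of myeloid cells, was 14.3-fold higher (adjusted p = 2.42e-06), Ly6c2 33.1-fold (adjusted p = 6.41e-05) and Itgam 5.87-fold (adjusted p = 0.00747). The BM total libraries had 1, 3 and 2 counts of Csf1r and 1, 2 and 1 of Ly6c2, so the size of both folds is imprecise. The BM level of Itgam, 6.55 ± 11.3 CPM, rested on 12 counts in BM_T replicate 2, with 0 in the other two, so its fold in total RNA depends on that library. Il1b, which encodes interleukin-1 beta, the macrophage elastase gene Mmp12 and the fungal receptor gene Clec4n had 0 counts in BM and were at least 99.4-fold, 118-fold and 100-fold higher, taking the floor as 3 counts over the group. Their LY6C levels, 190 ± 123, 227 ± 124 and 191 ± 94.5 CPM, were lowest in replicate 3 and highest in replicate 2. In the other direction, Slc4a1, the band 3 anion exchanger of red cells, was at 120 ± 44.9 CPM in BM and had 2 counts in LY6C, a ratio of 9040 with a counting interval of 2500 to 74700.

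Among the lists, 22 of 25 lysosome genes were higher in LY6C (23 when adjusted over the list alone), among them the granulin precursor Grn, 10.6-fold, and prosaposin, Psap, 7.72-fold. The list had an adjusted p = 6.64e-12, and 0.0958 with an estimated correlation. Immediate early and stress genes were higher for 14 of 18 members (16 adjusted over the list alone), with Klf6 at 21.9-fold (list adjusted p = 5.11e-14, and 0.0634 with an estimated correlation). Of 29 inflammatory genes, 18 were higher, also 18 adjusted over the list alone (list adjusted p = 1.59e-10, and 0.117 with an estimated correlation). MDSC suppressive function genes were higher for 16 of 24 (17 adjusted over the list alone), with the interleukin-4 receptor gene Il4ra 12.8-fold, Cybb of the NADPH oxidase 9.2-fold and the transcription factor gene Cebpb 23.2-fold (list adjusted p = 4.62e-10, and 0.0634 with an estimated correlation). Single BM libraries moved the log2 difference of Klf6 from 4.45 to between 3.83 and 5.12 and that of Cebpb from 4.53 to between 3.89 and 5.5.

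Further lists rose in part. Unfolded protein response genes were higher for 15 of 19 (15, with 1 lower, adjusted over the list alone; 0.0958) and glycolysis and hypoxia genes for 17 of 24 with 1 lower (18 and 1 adjusted over the list alone; 0.286), with Eno1 at 13.4-fold. Higher members numbered 12 of 26 in the interferon response (13 adjusted over the list alone; 0.497), 13 of 27 in monocyte and macrophage genes with 1 lower (13 and 1; 0.386) and 11 of 26 in neutrophil maturation (12, with 1 lower; 0.306). Cholesterol synthesis had 9 of 24 (11 adjusted over the list alone; 0.497). The ATF4 and amino acid response had 9 of 25 (10, with 1 lower, adjusted over the list alone; 0.153), ribosomal proteins 26 of 81 with 1 lower (28 and 1; 0.689), and MHC class II and dendritic cell genes 5 of 15 with 1 lower (6 and 1; 0.497). The last value in each bracket is the adjusted p with an estimated correlation.

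Lower in LY6C were 15 of 17 erythroid genes (15 adjusted over the list alone), with Klf1, the erythroid Krüppel-like factor, at least 828-fold and the spectrin gene Sptb at a log2 difference of −9.64 ± 0.70. The erythroid list had an adjusted p = 6.05e-45, and 9.13e-06 with an estimated correlation. All 7 mitochondrially encoded mRNAs were lower (7 adjusted over the list alone; 0.00766 with an estimated correlation), with mt-Nd5, a subunit of complex I, at 11.3 ± 3.57 against 3020 ± 950 CPM. Stroma and endothelium genes were lower for 8 of 11 (8 adjusted over the list alone; 0.0156 with an estimated correlation), including the collagen gene Col1a1 at 2.44 ± 2.13 against 3300 ± 1620 CPM. Megakaryocyte and platelet genes were lower for 5 of 8 (7 adjusted over the list alone; 0.0208), with the platelet integrin gene Itga2b at a log2 difference of −4.92 ± 0.79 (−5.83 without LY6C_T replicate 6). Small nucleolar and Cajal body RNAs were lower for 14 of 28 (16 adjusted over the list alone; 0.0411), among them Scarna8 at a log2 difference of −10.78 ± 0.88. B cell and plasma cell genes were lower for 8 of 15 (8 adjusted over the list alone; 0.0818), with the B lineage factor Ebf1 at −5.76 ± 1.06 (−7.97 without LY6C_T replicate 2).

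In the remaining lists, 3 of 9 stem and progenitor genes (3, with 1 higher, adjusted over the list alone) and 3 of 12 genes of basophils, mast cells and eosinophils (3 adjusted over the list alone) were lower, among them the eosinophil granule gene Prg2 at a log2 difference of −4.56 ± 1.03. Nuclear oxidative phosphorylation genes split into 16 higher and 4 lower of 73 (17 and 5 adjusted over the list alone), initiation factors into 10 higher and 3 lower of 38 (10 and 4 adjusted over the list alone), and nuclear noncoding RNAs into 3 higher and 1 lower of 8 (5 and 1 adjusted over the list alone). Other TOP mRNAs, whose translation follows mTOR, were higher for 5 of 23 (5 adjusted over the list alone). Cell cycle genes had 1 higher and 2 lower of 31 (0 and 2 adjusted over the list alone), with Mki67 at 80.8 ± 63.4 against 395 ± 134 CPM (adjusted p = 0.00682). Of 59 histone genes 1 was lower (0 adjusted over the list alone), and of 5 T cell and NK cell genes 1 was lower (1 higher and 1 lower adjusted over the list alone). In edgeR 0 of 8 primary granule genes passed (0 adjusted over the list alone). Histone and primary granule genes had positive medians, 0.50 and 1.74, while camera, which sets a list against all other genes, put both lists down (adjusted p = 0.286 and 0.743). Arg1 had 0 counts in BM and 98.6 ± 163 CPM in LY6C (adjusted p = 0.293), and Nos2 42.5 ± 72.1 CPM against 0 counts (adjusted p = 0.447).

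In all, 2913 genes were higher and 1050 lower in LY6C, and 757 of the higher ones had 0 counts in BM, where the median log2 difference of all genes was 1.64. Median-ratio factors put that median at 1.36, DESeq2 at 0.18 and limma at 0.05, and the higher share of calls went from 73.5% to 62.6%, 57.1% and 47.7%. The count was 1959 when the 6 compared libraries were fitted alone and 1919 when all libraries were thinned to 128251 counts. Erythroid, stromal and megakaryocyte transcripts, and the mitochondrial ribosomal RNA share given above, differed together with the group. Culture and sorting did so in every comparison with bone marrow. Their effects cannot be told apart from those of the population.

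LY6G cells set against bone marrow total RNA ask the same of the LY6G population. Csf1r was at 243 ± 14 CPM against 3.72 ± 1.44 (64-fold, adjusted p = 2.05e-07, n = 3 each, edgeR), Lyz2 17.6-fold higher (adjusted p = 9.47e-07), Ly6c2 22.9-fold (adjusted p = 0.000167) and Itgam 7.2-fold (adjusted p = 0.00297), against the same 12 counts of 1 BM library. The folds of Csf1r and Ly6c2 rest on the same few BM counts as in LY6C. Ly6g, the marker of the sort, was at 4.03 ± 4.07 against 1.92 ± 2.08 CPM (adjusted p = 0.586). Genes at 0 counts in BM included Mmp12, at least 163-fold higher, Clec4n, at least 142-fold, Il1b, at least 115-fold, and the cystine transporter gene Slc7a11, at least 106-fold. Lcn2, the neutrophil iron-binding protein lipocalin-2, was at 165 ± 39.4 against 15.7 CPM in BM, or 10.4-fold. Slc4a1 was lower with a ratio of 13400 (counting interval 3710 to 111000), Col1a1 by a log2 difference of −11.63, and mt-Nd5 by −8.89.

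The lists in LY6G had 23 of 25 lysosome genes higher (23 adjusted over the list alone; adjusted p = 0.0799 with an estimated correlation), 14 of 18 immediate early genes (16 adjusted over the list alone; 0.0751) and 18 of 29 inflammatory genes (19 adjusted over the list alone; 0.0751). MDSC suppressive function genes were higher for 16 of 24 (17 adjusted over the list alone; 0.0751). Lower were 15 of 17 erythroid genes (15 adjusted over the list alone; 7.13e-07), all 7 mitochondrially encoded mRNAs (7 adjusted over the list alone; 0.0108), 9 of 11 stroma and endothelium genes (9 adjusted over the list alone; 0.02) and 5 of 8 megakaryocyte genes (6 adjusted over the list alone; 0.0366). B cell genes were lower for 10 of 15 (10 adjusted over the list alone; 0.0751), small nucleolar and Cajal body RNAs for 15 of 28 (16 adjusted over the list alone; 0.0673) and cell cycle genes for 5 of 31 (3 adjusted over the list alone; 0.587). The peroxidase gene Mpo of primary granules was at 4.23 ± 2.35 against 58.3 ± 17.6 CPM (adjusted p = 0.0398), a call that was lost when any 1 of the 6 libraries was left out, with adjusted p from 0.0508 without BM_T replicate 3 to 0.122 without LY6G_T replicate 6.

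A total of 3043 genes were higher and 1331 lower in LY6G, of which 852 of the higher ones had 0 counts in BM. The median log2 difference of all genes, 1.63, was 1.49 with median-ratio factors, 0.32 in DESeq2 and 0.04 in limma, which called 6638 genes, and the higher share of calls went from 69.6% to 64.2%, 59.5% and 48.4%. Thinned to one depth, the comparison called 2311 genes.

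Polysomal RNA of LY6C against polysomal RNA of bone marrow asks the same question for transcripts under translation. Csf1r was at 303 ± 127 CPM against 20.5 ± 3.25 (14.7-fold, adjusted p = 1.82e-06, n = 3 each, edgeR), Lyz2 11.8-fold higher, Cybb 6.27-fold (adjusted p = 6.74e-06) and Cebpb 10.2-fold. Ly6c2 was 20.3-fold higher (adjusted p = 1.1e-05). Slc2a1, the glucose transporter GLUT1, was at 157 ± 153 against 2.37 ± 1.61 CPM, or 61.2-fold. Without LY6C_P replicate 6, the log2 difference of Ly6c2 fell from 4.34 to 3.09 and that of Slc2a1 from 5.94 to 4.77. Genes at 0 counts in BM included Mmp12, at least 1170-fold higher, the acute phase gene Saa3, at least 261-fold, and the neutrophil chemokine gene Cxcl3, at least 173-fold. The floors of Saa3 and Cxcl3 rest on LY6C_P replicate 6, at 510 and 320 CPM against at most 29.6 and 25.6 in the other two, and both calls were lost with the 6 compared libraries fitted alone (adjusted p = 0.119 and 0.143). On the lower side stood Slc4a1, with a ratio of 31500 (counting interval 5650 to 1240000), Col1a1 at a log2 difference of −10.52, the resistin-like gene Retnlg at 2.23 against 48.3 ± 18.2 CPM, and the nuclear noncoding RNA Malat1 at 715 ± 285 against 2060 ± 363 CPM (adjusted p = 0.00845).

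By list, 24 of 25 lysosome genes (24 adjusted over the list alone), 20 of 29 inflammatory genes (22 adjusted over the list alone), 15 of 18 immediate early genes (16 adjusted over the list alone) and 14 of 24 MDSC genes (17 adjusted over the list alone) were higher in LY6C polysomes. Each of these 4 had a camera adjusted p = 0.0817 with an estimated correlation. The interferon response had 17 of 26 higher (22 adjusted over the list alone; 0.487 with an estimated correlation) and cholesterol synthesis 14 of 24 (15 adjusted over the list alone; 0.418). Of 17 erythroid genes, 16 were lower (16 adjusted over the list alone), with an adjusted p = 2.14e-05 with an estimated correlation. Stroma genes were lower for 7 of 11 (7 adjusted over the list alone; 0.0657), megakaryocyte genes for 6 of 8 (6 adjusted over the list alone; 0.0691) and B cell genes for 9 of 15 (12 adjusted over the list alone; 0.0817). Mitochondrially encoded mRNAs were lower for 6 of 7 (7 adjusted over the list alone; 0.0817).

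Calls came to 2861 higher and 1592 lower, and 1679 in all at one depth, with a median log2 difference of 0.52 over all genes and 0.58 with median-ratio factors. Itgam was 3.52-fold higher (adjusted p = 0.0165), a call lost without LY6C_P replicate 2 (0.0791), BM_P replicate 2 (0.0726) or BM_P replicate 3 (0.068). Arg1 (adjusted p = 0.109) and Nos2 (adjusted p = 0.169), each at 0 counts in BM, did not pass.

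In LY6G polysomes, Csf1r was at 361 ± 133 CPM against 20.5 ± 3.25 in BM (17.6-fold, adjusted p = 6.7e-07, n = 3 each, edgeR), and Adgre1, which encodes the macrophage antigen F4/80, at 178 ± 115 against 4.38 CPM, or 40.1-fold (log2 difference 5.32, and 4.67 without LY6G_P replicate 6). Mmp12 was at least 1200-fold higher, Saa3 at least 327-fold, Cxcl3 at least 304-fold and the monocyte chemokine gene Ccl2 at least 147-fold, each against 0 counts. LY6G_P replicate 6 carried the floors of Saa3 and Cxcl3, at 323 and 279 CPM against at most 32.2 and 45.3 in the other two. Ly6c2 was 6.64-fold higher (adjusted p = 0.000481) and Itgam 5.19-fold (adjusted p = 0.00248), while Ly6g was at 5.01 ± 5.8 against 6.77 ± 2.63 CPM (adjusted p = 0.652, and 0.0357 with a log2 difference of −2.03 without LY6G_P replicate 6). Slc4a1 had 0 counts in LY6G and was at least 18200-fold lower. Mpo was at 6.39 against 191 ± 37.3 CPM (adjusted p = 0.00982), and the coagulation factor gene F13a1 at 8.92 against 153 ± 74.6 CPM.

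Its lists had 23 of 25 lysosome genes (24 adjusted over the list alone), 19 of 29 inflammatory genes (22 adjusted over the list alone) and 15 of 24 MDSC genes (16 adjusted over the list alone) higher, with adjusted p = 0.108, 0.108 and 0.127 with an estimated correlation. Lower were 17 of 17 erythroid genes (17 adjusted over the list alone; 2.59e-06), 13 of 15 B cell genes (13 adjusted over the list alone; 0.0776), 8 of 11 stroma genes (8 adjusted over the list alone; 0.0575) and 12 of 31 cell cycle genes (12 adjusted over the list alone; 0.521). Neutrophil maturation genes split into 7 higher and 6 lower of 26 (7 and 7 adjusted over the list alone; 0.917). Altogether 3137 genes were higher and 2176 lower, and 2131 were called at one depth. The median log2 difference of all genes was 0.45, and 0.68 with median-ratio factors.

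Polysomal set against total RNA of LY6C asks which transcripts are carried by polysomes beyond their abundance. Noncoding RNAs lay below the rest. Small nucleolar and Cajal body RNAs had a median log2 difference of −1.57 over 28 members (adjusted p = 6.9e-11, and 0.167 with an estimated correlation; 1 lower adjusted over the list alone) and 8 nuclear noncoding RNAs −0.94 (adjusted p = 9.96e-05, and 0.116 with an estimated correlation; 2 lower adjusted over the list alone). The 7 mitochondrially encoded mRNAs, which mitochondrial ribosomes translate, had −1.46 (adjusted p = 6.55e-07, and 0.164 with an estimated correlation, with 2 lower adjusted over the list alone). Their median was −0.32 without LY6C_T replicate 2. On the other side, 70 of 73 nuclear oxidative phosphorylation genes were positive, with a median of 0.58 (adjusted p = 2.5e-23, and 0.167 with an estimated correlation). Replication-dependent histones had 0.76 (adjusted p = 3.22e-08, and 0.515 with an estimated correlation) and glycolysis and hypoxia genes 0.67 (adjusted p = 4.3e-06, and 0.495 with an estimated correlation). Ly6c2 was at 283 ± 290 CPM in polysomal and 84.2 ± 9.2 in total RNA (log2 difference 1.75 ± 0.49, adjusted p = 1), and the difference was 0.47 without LY6C_P replicate 6.

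With the replicate number as a block, edgeR called 25 genes in LY6C, 24 of them lower in polysomal RNA, and 0 when the block was fitted in the 6 compared libraries alone. None of the 24 was annotated as protein coding, and they included the spliceosomal RNA Rnu5g (−3.43 ± 0.48, adjusted p = 0.0107) and the signal recognition particle RNA Rn7s1 (−6.27, adjusted p = 0.0316), and the 1 higher gene was the interferon-inducible Ifit1bl1 (1.91 ± 0.37, adjusted p = 0.0439). All 3 were chosen after their values were seen. The block also brought primary granule genes (median 0.60, adjusted p = 0.00299 against 0.221), interferon response genes (0.20, adjusted p = 0.0332 against 0.407) and cholesterol synthesis genes (0.30, adjusted p = 0.00849 against 0.0537) past the threshold, with adjusted p = 0.335, 0.35 and 0.35 with an estimated correlation. It ended the call of ribosomal protein genes, at a median of 0.21 (adjusted p = 0.143 against 0.0335, and 0.738 with an estimated correlation). Without the block 0 genes passed in edgeR, with 433 at an unadjusted p under 0.05. DESeq2 called 6 genes, limma 0, and the fit without a filter 56.

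In LY6G, polysomal against total RNA again put mitochondrial and noncoding RNAs lowest. The mitochondrially encoded mRNAs had a median of −1.34 (adjusted p = 4.22e-12, and 0.0213 with an estimated correlation; 4 lower adjusted over the list alone) and nuclear noncoding RNAs −1.17 (adjusted p = 9.36e-07, and 0.0213 with an estimated correlation; 1 lower adjusted over the list alone). With the block these values were −1.59 and −1.16, and the adjusted p with an estimated correlation became 0.125 and 0.0988. Small nucleolar and Cajal body RNAs had −1.11 (adjusted p = 2.07e-13, and 0.113 with an estimated correlation; 1 lower adjusted over the list alone), and nuclear oxidative phosphorylation genes 0.34 (adjusted p = 3.34e-10, and 0.487 with an estimated correlation). Ribosomal protein genes had a median of −0.21 (adjusted p = 0.0165, and 0.801 with an estimated correlation), opposite in sign to their 0.20 in LY6C.

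**Figure D4:**
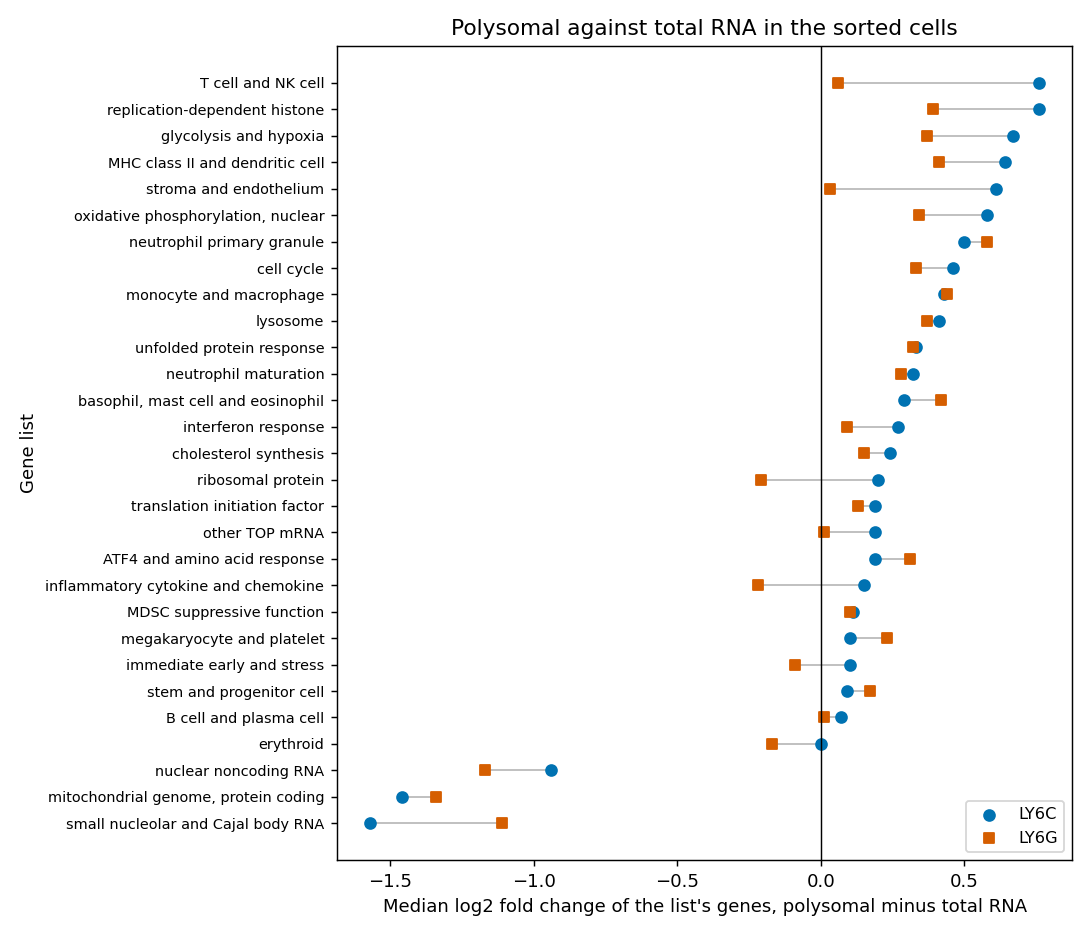
Median log2 difference between polysomal and total RNA (horizontal axis) of each gene list (vertical axis), with a circle for LY6C and a square for LY6G, 3 libraries per group. Mitochondrially encoded mRNAs (−1.46 and −1.34), nuclear noncoding RNAs (−0.94 and −1.17) and small nucleolar and Cajal body RNAs (−1.57 and −1.11) lie apart on the left.

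The block called 94 genes in LY6G, all lower in polysomal RNA, against 0 with the block in the 6 compared libraries alone, 0 without it, 254 at an unadjusted p under 0.05, 4 in DESeq2, 102 in limma and 29 without a filter. They included the long nuclear RNAs Malat1 (−1.46 ± 0.26, adjusted p = 0.0174) and Neat1 (−1.16 ± 0.20, adjusted p = 0.0174), the mitochondrial mt-Nd6 (−2.61 ± 0.33, adjusted p = 0.00284) and mt-Co1 (−2.01), and the ferritin genes Ftl1 (−1.43 ± 0.27, adjusted p = 0.0223) and Fth1 (−1.37 ± 0.31, adjusted p = 0.0439), whose translation iron controls. Pabpc1, the poly(A)-binding protein, was among them too (−0.92 ± 0.21, adjusted p = 0.0443), and all 7 were chosen after their values were seen. Under the block, primary granule (median 0.62, adjusted p = 0.000583 against 0.0716), cholesterol synthesis (0.20, 0.0425 against 0.073) and ATF4 genes (0.27, 0.0469 against 0.0698) leaned to polysomes and inflammatory genes away from them (−0.16, 0.0281 against 0.28). Their adjusted p with an estimated correlation was 0.353, 0.516, 0.353 and 0.422. Across genes, the polysomal minus total differences of LY6C and LY6G had r = 0.66 and rho = 0.67, and those of BM had r = 0.04 with LY6C and 0.02 with LY6G.

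In bone marrow, polysomal RNA held less mitochondrial mRNA than total RNA. All 7 mitochondrially encoded mRNAs were lower (7 adjusted over the list alone; adjusted p = 3.14e-32, and 0.000711 with an estimated correlation), mt-Nd5 at 166 ± 37.9 against 3020 ± 950 CPM (log2 difference −4.19 ± 0.46, adjusted p = 0.000203, n = 3 each, edgeR) and mt-Co1 by −3.92. Lower as well were the Cajal body RNA Scarna8, at 1.24 ± 0.6 against 96.7 ± 62.8 CPM (adjusted p = 0.000203), and the minor spliceosome RNA Rnu11, at 3.89 against 139 ± 97.8 (adjusted p = 0.000609). Higher in polysomes were the NADPH oxidase gene Ncf1, 96.2 ± 4.53 against 25 ± 11.5 CPM (3.88-fold, adjusted p = 0.0053), and Cox6b1 of respiratory complex IV, 7.06-fold (adjusted p = 0.00628). Ddhd1, a phospholipase, was at 22.5 ± 5.64 CPM against 0 counts in total RNA, at least 11.5-fold higher (adjusted p = 0.00083), and the blood cell transcription factor gene Lyl1 at least 8.25-fold.

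Other TOP mRNAs had 2 higher of 23 (11 adjusted over the list alone; adjusted p = 0.000281, and 0.927 with an estimated correlation), nuclear oxidative phosphorylation 3 of 73 (11 higher and 1 lower adjusted over the list alone) and ribosomal proteins 3 of 81 (4 adjusted over the list alone). One erythroid gene of 17 was higher, Epb42 of the red cell membrane at least 6.01-fold (adjusted p = 0.0299; 4 adjusted over the list alone), with an adjusted p = 0.246 for the list with an estimated correlation. Epb42 lost its call when any 1 of the 6 libraries was left out, with adjusted p from 0.0519 without BM_T replicate 1 to 0.0886 without BM_P replicate 1. Csf1r was 5.4-fold higher (adjusted p = 0.0275), and lost its call in the same way, from 0.0523 without BM_P replicate 2 to 0.0872 without BM_T replicate 1.

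Counts were 368 higher and 113 lower, and 119 of the higher genes had 0 counts in BM total RNA, the group with fewer coding counts. The total of 481 fell to 125 without BM_P replicate 1, 238 without BM_T replicate 2 and 257 without BM_P replicate 3, to 110 at one depth, 139 in limma, 145 in the 6 libraries alone and 200 with median-ratio factors, which put the median of all genes at 0.13 in place of 0.55. The balance turned too, to 85 higher and 422 lower in DESeq2, 67 and 133 with median-ratio factors, 47 and 63 at one depth and 33 and 112 in the 6 libraries alone.

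Translational efficiency, the polysomal minus total log2 difference of 1 cell kind minus that of another, asks whether use by polysomes changes beyond RNA level. Between LY6G and LY6C, Ly6c2 had a difference of −1.08 ± 0.68 (0.2 without LY6C_P replicate 6), Itgam 0.27 ± 0.70 and Arg1 −0.06 ± 3.48 (adjusted p = 1 each, n = 3 per group, edgeR). Ribosomal protein genes leaned to LY6C with a median of −0.37 and 6 of 81 positive (adjusted p = 1.16e-10), as did nuclear oxidative phosphorylation genes at −0.32 (adjusted p = 3.03e-09), histones at −0.32 (adjusted p = 0.005), other TOP mRNAs at −0.24 (adjusted p = 0.00784) and immediate early genes at −0.18 (adjusted p = 0.047). For each of these 5 the adjusted p was 0.95 with an estimated correlation. With the replicate block, inflammatory genes (median −0.27, adjusted p = 8.68e-05 against 0.0592), glycolysis genes (−0.25, 0.0173 against 0.0592), interferon response genes (−0.21, 0.0436 against 0.746) and mitochondrially encoded mRNAs (−0.40, 0.0173 against 0.209) also leaned to LY6C, with adjusted p = 0.778, 0.888, 0.861 and 0.861 with an estimated correlation. No gene passed: edgeR called 0, with 7 at an unadjusted p under 0.05, DESeq2 and limma called 0, and the fit without a filter called 5.

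Against bone marrow, mitochondrially encoded mRNAs had the higher polysomal minus total difference in sorted cells. In each population 1 of 7 members was called (6 adjusted over the list alone). The camera adjusted p was 0.0142 in LY6C and 0.0379 in LY6G with an estimated correlation. Mitochondrial ribosomes translate these mRNAs, so this difference does not measure how well they are translated. The called member was mt-Nd5, at a log2 difference of 2.93 ± 0.59 in LY6C (adjusted p = 0.0399, n = 3 per group, edgeR) and 2.85 ± 0.59 in LY6G (adjusted p = 0.0345). Tnfrsf14, the lymphocyte receptor HVEM, was higher by 3.63 ± 0.63 in LY6C and 4 ± 0.64 in LY6G, with 721 CPM in BM total and 40.5 CPM in BM polysomal RNA. Its counts were 184, 690 and 312 in BM total and 120, 62 and 146 in BM polysomal libraries. Whether all of these reads stem from Tnfrsf14 was not checked, since no reads were mapped again, so the difference may not reflect use by polysomes. Polh, a DNA polymerase of damage bypass, was higher by 3.97 and 4.02. Ncf1 was lower, at a log2 difference of −2.11 ± 0.46 in LY6C and −2.07 ± 0.46 in LY6G. Ddhd1 had the lowest values in both, with 0 counts in BM total and 178 in BM polysomal RNA against 33.6 CPM in LY6C polysomes and 41 CPM in LY6C total RNA, so its fitted difference depends on the prior count. Nuclear noncoding RNAs had no called member (2 lower in LY6C and 3 in LY6G adjusted over the list alone), with adjusted p = 0.179 and 0.119 with an estimated correlation.

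In LY6C, 12 genes had higher and 36 lower efficiency than in bone marrow, and 25 of the 36 had a group at 0 counts. In LY6G, 14 were higher and 45 lower, and 28 of the 45 had a group at 0 counts. The median over all genes was −0.64 in LY6C and −0.65 in LY6G, and −0.38 in both with median-ratio factors. The balance turned in LY6C to 154 higher and 30 lower in DESeq2 and 19 and 15 with median-ratio factors, and in LY6G to 155 and 45 and to 22 and 17. The LY6C count of 48 became 1, Ddhd1, without BM_P replicate 1 and 95 without BM_T replicate 1, and was 28 without BM_T replicate 2. Leaving out LY6C polysomal replicates 2, 3 and 6 gave 17, 19 and 22, and LY6C total replicates 29, 18 and 18. The LY6G count of 59 became 106 without BM_T replicate 1 and 23 without BM_P replicate 1, 20, 12 and 19 without LY6G polysomal replicates 2, 3 and 6, and 16, 23 and 16 without the total ones. Ddhd1 passed in every such fit of both comparisons. In LY6C, Tnfrsf14 and Polh lost their calls without BM_P replicate 1 (adjusted p = 0.0548 and 0.061). The call of mt-Nd5 was lost in most fits, with adjusted p up to 0.0996 in LY6C (without BM_P replicate 1) and 0.116 in LY6G (without LY6G_P replicate 2). Ncf1 was lost in most fits too, with up to 0.103 in LY6C (without LY6C_P replicate 6) and 0.126 in LY6G (without LY6G_P replicate 3).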

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

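The thinned fit and the explanations of depth, scaling and abundant genes were chosen only after the counts had been seen, while the tests of efficiency were planned. A tested difference between groups flagged each result here, namely that polysomal minus total RNA differed between sorted cells and bone marrow. In LY6C this held for 48 genes. Those with higher efficiency in LY6C included Osgep (4.68), Polh (3.97), Tnfrsf14 (3.63), Zfp626 (3.41), Optn (3.11), mt-Nd5 (2.93), Cfap36 (2.72) and Brap (2.32). The value of Osgep, here and in LY6G, rests on 4 counts in BM polysomal and 19 in BM total RNA. For none of these genes was it checked whether reads in BM total RNA were shared with other loci. Ncf1 was lower (−2.11). Plscr3 (−11.61), Aqr (−11.8), Vps28 (−11.86), Senp2 (−12.09), Polr3a (−12.11), St13 (−12.28), Arfrp1 (−12.82) and Ddhd1 (−13.33) had 0 counts in BM total RNA, so their sizes depend on the prior count. The mitochondrially encoded mRNAs differed as a list, with an adjusted p = 0.0142 with an estimated correlation.

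In LY6G the difference held for 59 genes. Osgep (4.65), Polh (4.02), Tnfrsf14 (4), Optn (3.4), Zfp626 (3.17), mt-Nd5 (2.85), Brap (2.34) and Vps35l (2.23) had higher efficiency, and Ncf1 (−2.07) and Rps24 (−2.74) lower. The genes with 0 counts in BM total RNA were Aqr (−11.91), Plscr3 (−11.95), Vps28 (−11.95), Senp2 (−11.96), Polr3a (−12.05), St13 (−12.23), Arfrp1 (−12.75) and Ddhd1 (−13.33). For the mitochondrially encoded mRNAs the adjusted p was 0.0379 with an estimated correlation. The BM libraries are the same in both comparisons, so the 2 sets of genes are not independent.

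The polysomal minus total contrast of bone marrow enters both comparisons, and 76.5% of its calls are higher in polysomal RNA. At one depth the higher share was 42.7%, so unequal depth may account for the surplus of higher genes. With median-ratio factors it was 33.5%, but these factors shift every gene of the contrast alike (median of all genes 0.13 in place of 0.55), so scaling factors and a general shift of the RNA cannot be told apart. Leaving out the abundant and mitochondrial genes gave 74.4%. Removing them after sequencing does not return the reads they took. The fit therefore cannot decide whether a few genes taking most of the counts lie behind the surplus. The higher genes that stayed called, 47 at one depth and 67 with median-ratio factors, were all among those of the planned fit. No biological explanation was tested for the surplus.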

How the results depend on the processing

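Of the alternatives, the block in the compared libraries alone, thinning, leaving out replicate 6 and the noncoding classes were chosen after seeing the data, and the cause was not tested for any moved result except where fewer genes or libraries entered. No call changed sign in a fit with all libraries. With 1 library left out, 2 called values changed sign, besides values of genes that were not called: Hist3h2ba in LY6C minus BM, total RNA, ranged from −9.8 (without LY6C_T replicate 2) to 4.51 (without BM_T replicate 3) against −5.51, and Hist3h2ba in LY6G minus BM, total RNA, from −5.23 (without LY6G_T replicate 3) to 5.6 (without BM_T replicate 3) against −4.41. Among named genes, 16 lost and 1 gained a call in DESeq2, 44 and 2 in limma, 22 and 0 with median-ratio factors, 9 and 13 without a filter, and 43 and 0 at one depth. Among lists, 143 calls were lost with an estimated correlation and 81 in fry. The fit without the block left 2-fold changes out of reach, with at most 3% recovered in any simulated comparison. It recovered 8-fold changes for 70% of genes in LY6C minus BM total RNA and 88% in LY6G minus LY6C total RNA. On the same simulated counts the block recovered 34% and 29% of 2-fold changes in LY6G minus LY6C total and polysomal RNA. It recovered 25% and 29% in polysomal minus total RNA of LY6C and LY6G. In sorted cells the limit thus lay partly in a model without the pairing. Even with the block, recovery was 2% in efficiency of LY6G minus LY6C and at most 4% in comparisons with BM.

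Median-ratio factors called 200 genes (67 higher, 133 lower) in polysomal minus total RNA of BM and 39 (22 higher, 17 lower) in LY6G minus BM efficiency. Without a filter, calls were 76 and 88 in LY6G minus LY6C total and polysomal RNA, 56 and 29 in polysomal minus total RNA of LY6C and LY6G, and 5, 93 and 105 in efficiency of LY6G minus LY6C, LY6C minus BM and LY6G minus BM. The 5 were Rn7s1 (higher), Svs4, Svs5, Svs6 and Pate4 (lower), chosen after their values were seen. The stricter filter called 87 in LY6C minus BM efficiency, and moved the correlation of LY6C and LY6G polysomal minus total differences from 0.66 to 0.79 with fewer genes tested. At one depth, calls were 1919 and 2311 in total RNA of LY6C and LY6G minus BM, 1679 and 2131 in polysomal RNA, 110 (47 higher, 63 lower) in polysomal minus total RNA of BM, and 6 and 3 in efficiency.

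The replicate block called 25 and 94 genes in polysomal minus total RNA of LY6C and LY6G, and 0 and 0 in the compared libraries alone, and changed no other call in sorted cells beyond those given with the comparisons. For bone marrow, where pairing by number was not shown (correlations 0.03, 0.01 and 0), it called 844 in polysomal minus total RNA. In efficiency of LY6C and LY6G minus BM it called 164 and 217. DESeq2 called 6 and 4 genes in polysomal minus total RNA of LY6C and LY6G, all lower, and 184 (154 higher, 30 lower) and 200 (155 higher, 45 lower) in efficiency against BM. In limma the counts were 1 in LY6G minus LY6C total RNA (Hbb-bt, lower, chosen after its values were seen), 6638 in LY6G minus BM total RNA, 102 and 139 in polysomal minus total RNA of LY6G and BM, and 15 and 89 in efficiency against BM. The compared libraries alone gave 1959 in LY6C minus BM total RNA, 145 in polysomal minus total RNA of BM, and 4 and 19 in efficiency. With the block added they gave 734 and 1517 in total RNA of LY6C and LY6G minus BM, 2787 in polysomal RNA of LY6C minus BM, 225 in polysomal minus total RNA of BM and 116 in LY6G minus BM efficiency.

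With 1 library left out, counts ranged from 0 to 0 in LY6G minus LY6C total and polysomal RNA, 125 to 499 in polysomal minus total RNA of BM, 1 to 95 in LY6C minus BM and 12 to 106 in LY6G minus BM efficiency. Without replicate 6, calls were 4 and 1 in LY6G minus LY6C total and polysomal RNA (all lower, with Hbb-bs in both, chosen after its values were seen), and 4 and 6 in efficiency against BM. Totals not given here stayed within 1.5 times the planned fit.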

Other observations

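Interferon response genes, which mark a reaction to viral or nucleic acid signals, were higher in the libraries numbered 6 for 26 of 26 members in both populations, with medians of 2.64 in LY6C and 1.57 in LY6G against the other 2 numbers. Cell cycle genes were lower there, with 1 of 31 members higher in LY6C (median −1.34) and 0 in LY6G (−2.45), and glycolysis and hypoxia genes were higher for 23 and 22 of 24 (1.04 and 0.6). Some markers of other cells were higher in number 6 too: megakaryocyte genes for 7 of 8 in each population (1.32 and 0.95), basophil, mast cell and eosinophil genes for 8 and 11 of 12 (0.66 and 1.74), and stroma genes for 8 and 10 of 11 (0.92 and 0.5). Some stroma genes rested on few counts, such as Sparc with 6 and 4 in the polysomal and total LY6C libraries numbered 6. Erythroid genes did not follow in LY6C, with 7 of 17 higher (median 0), and 12 of 17 were higher in LY6G (0.17). B cell genes were higher for 14 of 15 in LY6G (1) and 3 of 15 in LY6C (−1.47). Number 3 had 8 of 8 primary granule genes higher in LY6C (3.57) and 7 of 8 in LY6G (1.03), 31 of 31 cell cycle genes in each (1.63 and 1.69), and 0 and 1 of 26 interferon genes (−1.57 and −0.5). Number 2 had 16 of 18 immediate early genes higher in LY6C (0.97) and 18 of 18 in LY6G (0.78), and B cell genes higher for 14 of 15 in LY6C (1.93) and 6 of 15 in LY6G (−0.11). It too was low in interferon genes, with 2 and 0 of 26 higher (−0.96 and −1.08). Each number is set against the other 2, so a rise in number 6 by itself lowers the values of numbers 2 and 3. What each number stands for beyond a biological replicate is not given in the sources used here, and with 1 library of each fraction per population and number no test was made.

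Annotated noncoding classes, grouped after seeing the data, lay lower in polysomes than in total RNA of sorted cells. Small nuclear RNAs, the RNA of the spliceosome, had a median of −1.47 in LY6C and −1.81 in LY6G over 41 members (adjusted p = 0.0052 and 0.00199 with an estimated correlation). Long intergenic RNAs had −0.56 and −0.59 over 325 (adjusted p = 0.0134 and 0.00352), antisense RNAs −0.47 and −0.56 over 249 (0.00554 and 0.00079) and small nucleolar RNAs −1.06 and −1.01 over 57 (0.0323 and 0.0124). Small Cajal body RNAs had −0.62 and −0.66 over 13 members (0.585 and 0.253).

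The explanations weighed below were chosen only after the results were seen. Mitochondrially encoded mRNAs lay lower in polysomal RNA in all 3 kinds of cells. Polysomal RNA also held less mitochondrial ribosomal RNA per nuclear coding count in 9 of 9 matches by number. In BM, where pairing was not shown, it was at most 17.4 in any polysomal against at least 206 in any total library. Mitochondrial RNA left outside the polysome fractions may therefore account for the medians. The ratio cannot decide this, since libraries were made after depletion of ribosomal RNA and it also depends on what the depletion left. Within LY6C total RNA alone it ran from 0.0178 (replicate 2) to 0.822 (replicate 3). In LY6C the median came to −0.32 without LY6C_T replicate 2, against −1.46 with it, but that fit kept its polysomal partner. With the replicate block the median was −1.25. In number 6, 1 CPM was 23.9 counts in LY6C polysomal and 24.1 in LY6C total RNA. There all 7 mRNAs had fewer polysomal counts, such as 496 against 1510 for mt-Co1 and 120 against 196 for mt-Nd5. These values argue against LY6C_T replicate 2 as the whole cause, though the size of the median depends on it. In LY6G single libraries moved the median of −1.34 to between −2.57 (without LY6G_P replicate 2) and −0.99 (without LY6G_P replicate 6), and in BM the medians ran from −4.4 to −3.84. The medians of LY6G and BM thus stayed negative whichever library was left out, which speaks against 1 library as their whole cause. No biological explanation was tested.

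Arg1 and Nos2, which degrade or use arginine, were high in the 4 sorted libraries numbered 6. The highest Arg1 among the other 8 was 16.9 CPM and the lowest of the 4 was 206 CPM, or 12.2-fold. The ribosomal RNA share of the library is argued against. LY6G_P replicate 6 had the lowest share, 3.78%, with Arg1 at 477 CPM, while LY6C_T replicate 3, at 61.1%, had 2.55 CPM. Set against the library of another number nearest in share, each of the 4 was at least 18.7-fold higher in Arg1 and Nos2, beyond the 6.64-fold and 2.57-fold ranges of the other 8. A swap of some libraries between numbers is argued against as well. Over all tested genes the deviations from the group means correlated at 0.36 or above between libraries numbered 6, and at −0.09 or below between these and other numbers in other groups. A culture or batch behind the number 6 and a difference between biological replicates cannot be told apart, since all 4 high libraries carry that one number, and a label wrong for all 4 stays open too.

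Transcripts of the seminal vesicle, a list of 8 genes chosen once the unfiltered fit was known, had 322 counts in LY6G_T replicate 2, 261 in LY6C_P replicate 3, 44 in LY6G_P replicate 2, 34 in LY6G_T replicate 6, 21 in LY6C_T replicate 3 and 14 in LY6C_T replicate 2. The other sorted libraries had at most 8 counts and the bone marrow libraries 0.

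Splits of each comparison's libraries into 3 and 3, the actual one included, number 10, too few for a share under 0.05. The actual grouping called most genes, 1 of 10 splits with the highest other at 0, in LY6C minus BM and LY6G minus BM in total RNA, in polysomal RNA and in efficiency, and in polysomal minus total RNA of BM. In LY6G minus LY6C all 10 splits called at least the 0 genes of the actual one, with highest others of 3 in total RNA, 1 in polysomal RNA and 0 in efficiency. For polysomal minus total RNA all 10 did too, with highest others of 65 in LY6C and 0 in LY6G. The 65 arose with LY6C_P replicate 2, LY6C_T replicate 2 and LY6C_T replicate 6 set against the rest, which points to a structure of the samples. Where numbers pair, the other splits that part every pair called 0 genes, and the remaining splits keep a pair together on each side.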
